A study of Homo sapiens with 18 samples.

How the data were processed

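The series profiled FLAG-tagged MYC by eCLIP in U2OS cells that lack endogenous MYC and express wild-type, 3A or 7A MYC under doxycycline control. Per the labels' protocols, cells were treated for 24 h with 1 µg/mL doxycycline or with saline, irradiated with ultraviolet light and lysed, and the lysate was treated with RNase I and a DNase before precipitation of the tagged protein. Samples were grouped by allele, treatment and library type from their titles, which gave 12 groups with 12 immunoprecipitated and 6 input libraries. Per the submitters' processing notes, MACS2, cutadapt and BWA were used with the build hg38. Their versions, settings and roles, the control used for peak calling, and whether replicates were pooled are not given in the sources used here.

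The deposited files used here are 3 peak lists in narrowPeak layout, 1 for each allele with doxycycline. Each deposited peak has a fold enrichment, which is a ratio over a control or background that the authors' sources used here do not name. The authors also gave each peak a −log10 q value, and the lowest was 2.04 in the wild-type list, 2.34 in 3A and 2.90 in 7A. The position of the summit is an offset in bp from the peak's start in the deposited lists. All 3 lists give a strand. Fold enrichments and −log10 q values of different lists were not compared, since depth, control and cutoff are unknown. Depth per sample is unknown, and intervals on shares of peaks cover counting error over peaks only. A deeper or cleaner library yields more peaks, so differences in list length can come from sequencing or precipitation as well as from binding. Reads from similar copies, such as histone genes of the same type and pseudogenes of ribosomal protein genes, can be placed at the wrong copy.

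Coordinates were turned to 1-based positions. Peaks were assigned to genes with a RefSeq gene table of GRCh38.p14, the assembly of hg38, which held 59716 placed genes with their spans and types. It gives no exons, untranslated regions or strands, and no genome sequence was used here. The annotation classes planned before the data were examined were therefore reduced to the type of the host gene, the shortest gene that holds the summit. The planned tests of GC content and of 5-base words were not run for the same reason. The start of a host gene was taken as its lower end for a peak on the plus strand and its upper end for a peak on the minus strand. Of 440 gene names in the 11 lists fixed beforehand, 425 matched the table. The 15 unmatched names were all of the list of genes of mitochondrial DNA, which was not tested. The MYC target list was recalled from a published collection without MYC itself.

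Overlaps required at least 1 bp. Peaks of a mutant were moved 1000 times to a uniform position within the host gene, or for peaks outside genes within the chromosome up to its last annotated gene, and p is one-sided. Host genes were taken with their introns, since no exons were given. Random overlaps and random shares near gene starts can therefore be lower than with placement in exons. Fold enrichments within the wild-type list were compared on the log2 scale by a two-sided permutation test of means with 100000 resamples. Shares between lists were compared by two-sided Fisher's exact tests. Gene lists were compared with 10000 random sets matched on coding class and on length in 10 bins, one-sided in each direction. Adjustment was by Benjamini-Hochberg, and the threshold was 0.05. Peaks were the items in all tests, so p-values describe these lists and not the spread between cultures. Shares of peaks per gene list and widths were compared after the data had been seen. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.

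The tests were tried on simulated data. Of 40 simulated 3A lists of 103 peaks placed at random, 2 passed the overlap test, and all 40 passed when a portion of the peaks was put on wild-type peaks. The random lists were placed by the rule of the test itself, so they do not show how it behaves for peaks confined to exons. Of 40 random sets of 60 genes, 2 passed the gene list test, and all 40 passed when a portion of each set was drawn from genes with a peak. The permutation test on the 2149 wild-type peaks called 0 of 40 random splits and all 40 with 0.5 added on the log2 scale. The observed difference was smaller, 0.32, and power at that size was not tried.

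Genes named in the text were chosen by a rule fixed before the data were examined. For each list it took the hosts of the 10 peaks with the highest fold enrichment and the highest −log10 q and the 5 genes with the most peaks. It also took the first 10 genes with a peak in all 3 lists, MYC, up to 6 members per gene list, and up to 10 peaks per mutant that no wild-type peak overlaps. Among the items the rule selects, a single gene was left out of the text and is not reported here. The alternatives were a −log10 q of at least 5, the upper part of each list by fold enrichment, the 22 autosomes with X, merging within 100 bp, stricter overlaps, other placements, equal numbers of peaks, other class rules, distances of 1000 and 200 bp, and no length match.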

Results

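RNA bound by MYC, a transcription factor of the basic helix-loop-helix leucine zipper family, was mapped by enhanced crosslinking and immunoprecipitation with sequencing (eCLIP). In this assay ultraviolet light links protein to RNA in living cells, the protein is precipitated, and the RNA fragments that come down with it are sequenced. The cells were U2OS, a human osteosarcoma line, in which the endogenous MYC had been knocked out and a FLAG-tagged MYC could be switched on with doxycycline. There were 3 MYC alleles, wild type and the mutants named 3A and 7A, and the labels do not say which residues the mutants change. The series comprised 18 libraries in 12 groups. Each allele had 2 immunoprecipitated libraries and 1 input library after 24 h with 1 µg/mL doxycycline, and the same numbers without it. The 3 peak lists analysed here are those of the doxycycline-treated immunoprecipitates, 1 list per allele. Peak lists of cells without doxycycline were not analysed here, so no background was measured in uninduced cells. With 1 list per allele there was no replicate check on any value, and the sequencing depth behind the lists is unknown. Coordinates are those of hg38, and each fold enrichment is the authors' value for that peak, used only within its own list.

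The wild-type list held 2149 peaks, the 3A list 103 and the 7A list 88. The wild-type list was thus 20.9 times as long as the 3A list and 24.4 times as long as the 7A list. No test was made of these counts, which have no replicates. Wild-type peaks had a median width of 165 bp and lay in 1426 host genes, the host being the shortest annotated gene that holds the summit. The 3A peaks had a median width of 171 bp and 76 host genes. The 7A peaks were wider, with a median of 202 bp and 61 host genes, and 29.5% of them exceeded 400 bp against 5.86% of wild-type peaks. The mean log2 width of the 7A peaks was 0.58 above that of the wild-type peaks (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). For 3A the difference was 0.16 (two-sided permutation test, p = 0.018). Depth, control and cutoff are unknown and may also affect width, and neighbouring wide peaks can be parts of 1 region. All peaks lay on the autosomes and chromosome X, and the mitochondrial chromosome had none. Wild-type peaks did lie in 4 nuclear pseudogenes of mitochondrial genes. Of these, MTRNR2L1 had a peak in all 3 lists, and its peak had the highest −log10 q of the 7A list (778). Whether reads of mitochondrial RNA were placed there was not tested.

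The strongest wild-type peaks lay at MYC and at the start of PGK1, which encodes the glycolytic enzyme phosphoglycerate kinase. The first MYC peak, on chromosome 8 from 127738264 to 127739085, had a fold enrichment of 563 and a −log10 q of 4197. The second, from 127740393 to 127741030, had a fold enrichment of 355. Both lay on the plus strand inside the annotated gene, which spans 127735434 to 127742951. The PGK1 peak, on chromosome X from 78103815 to 78104399, had a fold enrichment of 331, and 74.0% of its length lay upstream of the annotated gene start at 78104248. The other 2 wild-type peaks in PGK1 had fold enrichments of 7.0 and 6.88. The highest fold enrichment elsewhere in the wild-type list was 44.8. The same 3 positions were also peaks in both mutant lists, with starts that differed by at most 27 bp between lists. The cells carry a MYC transgene, so reads at MYC can come from it.

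**Figure D1:**
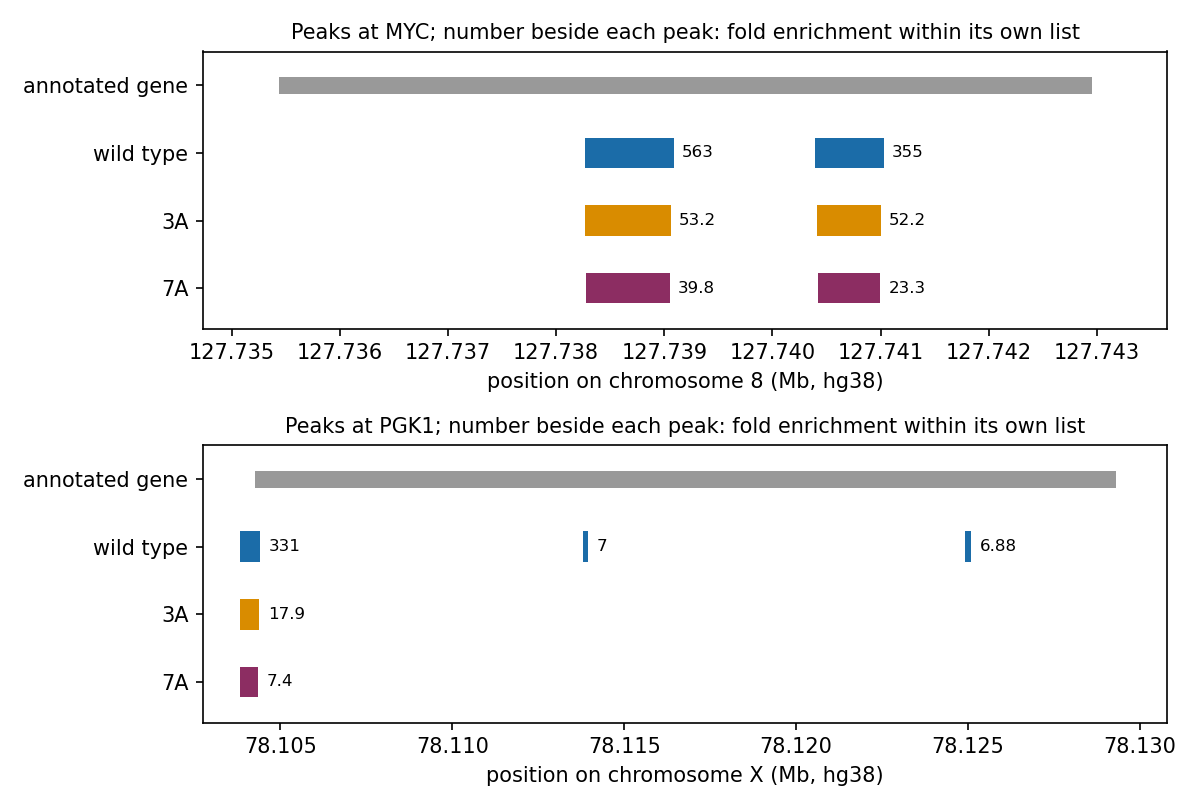
Peaks at MYC (top) and PGK1 (bottom) in the 3 lists, drawn to scale along the chromosome in Mb except that the narrowest peaks are widened to stay visible; grey bars are the annotated genes and the number beside each peak is its fold enrichment within its own list. Wild-type fold enrichments were 563 and 355 at MYC and 331 at the start of PGK1, and all 3 positions recur in both mutant lists.

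After these, the wild-type peaks of highest fold enrichment lay in genes of metabolism and protein synthesis. They included RPS21P4, a pseudogene of a ribosomal protein gene (44.8), LDHB, a lactate dehydrogenase subunit (40.8), SPOCK3 (38.3), the nucleoside diphosphate kinase gene NME1 (37.1), the transferrin receptor gene TFRC (32.0) and the inorganic pyrophosphatase gene PPA1 (31.6). Ranked by −log10 q, the peaks at MYC and PGK1 were followed by RPPH1, the RNA component of ribonuclease P (1189), RMRP, the RNA component of ribonuclease MRP (1102), MTRNR2L1 (708), SCARNA28 (386), the linker histone gene H1-4 (379), the enolase gene ENO1 (249) and the ribosomal protein gene RPL8 (244). The fold enrichments of RPPH1 and RMRP were only 3.61 and 1.94. The genes with the most wild-type peaks were the pyruvate kinase gene PKM with 12, the fatty acid synthase gene FASN with 11, ENO1 with 9, the elongation factor gene EEF2 with 9, and SCD, a fatty acid desaturase gene, with 8. SCD was tied with EEF1A2, EIF4G1 and HSP90AB1, which also had 8.

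The wild-type peaks lay mostly in protein-coding genes. These held 1870 of the 2149 summits (87.0%, 95% Wilson interval 85.5 to 88.4), pseudogenes held 161 (7.49%), long non-coding RNA genes 82 (3.82%) and small non-coding RNA genes 8 (0.372%), and 28 (1.30%) lay in no annotated gene. The non-coding shares depended on the host rule. With protein-coding genes taken first, long non-coding RNA genes held 26 (1.21%), small non-coding RNA genes 4 (0.186%) and pseudogenes 113 (5.26%). Of the 161 pseudogene peaks, 58 lay in pseudogenes of ribosomal protein genes, which are near-identical to their parents, so the gene of origin is uncertain there. Protein-coding genes held a lower share of the 7A peaks, 71.6% (63 of 88; two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 10 tests, adjusted p = 0.000895). By the same exact test the 7A list had higher shares in long non-coding RNA genes, 11.4% (adjusted p = 0.00893), and outside genes, 12.5% (adjusted p = 1.27e-06). In the 3A list, by the same exact test, 84.5% lay in protein-coding genes (adjusted p = 0.505), 5.83% lay outside genes (adjusted p = 0.00936) and 2.91% in small non-coding RNA genes (adjusted p = 0.0235). None of these differences passed when each mutant was set against an equal number of wild-type peaks of highest −log10 q, where the lowest adjusted p was 0.0894. With fewer peaks compared, the 7A differences were still 10.2 percentage points for long non-coding RNA genes (11.4% against 1.14%) and 10.2 outside genes (12.5% against 2.27%). The 3A difference in small non-coding RNA genes also ended under 3 other settings (Fisher's exact test, adjusted p from 0.0551 to 0.342).

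Wild-type and 3A peaks gathered at gene starts, and 7A peaks did not do so detectably. Among wild-type peaks in a gene, 948 of 2121 summits (44.7%) lay within 500 bp of the start of the host gene, against 11.6% ± 0.502 (SD over 1000 random placements within the same genes; one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Among 3A peaks it was 46 of 97 (47.4%) against 24.8% ± 2.37 at random (permutation p = 0.000999). Among 7A peaks it was 7 of 77 (9.09%) against 8.93% ± 1.96 (permutation p = 0.587). The 7A share was below the wild-type share by two-sided Fisher's exact test (p = 3.32e-11), and the 3A share was not shown to differ from it (p = 0.603). In protein-coding hosts of at least 5 kb, 53.3% of 1519 wild-type summits lay in the first 5th of the gene and 20.7% in the last. Of 56 3A summits, 41.1% lay in the first and 30.4% in the last, and 14.5% of 55 7A summits lay in the first and 38.2% in the last. The annotation used here gives no strand, so the strand of the peak was taken as that of the gene.

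**Figure D2:**
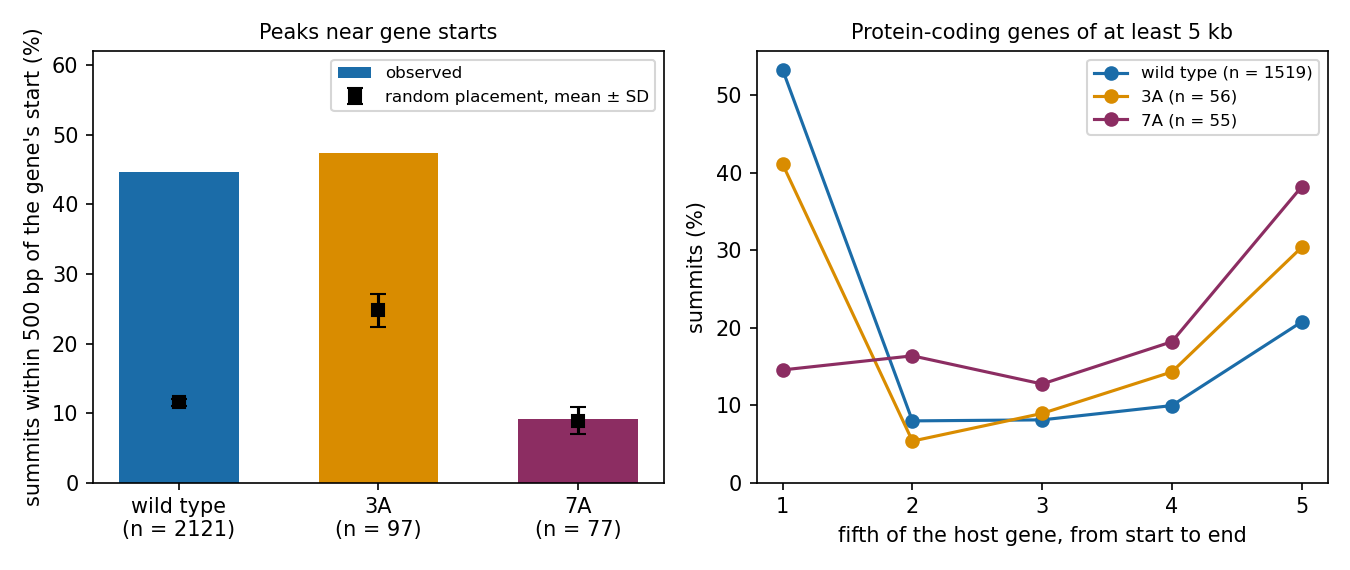
Left, bars give the percentage of summits within 500 bp of the host gene's start in each list, and black squares with error bars give the mean ± SD of 1000 random placements within the same genes; right, points give the percentage of summits in each 5th of protein-coding host genes of at least 5 kb. Wild type (44.7%) and 3A (47.4%) lie above random placement, and 7A (9.09%) lies at it.

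Genes of the cytosolic ribosome stood out among the gene lists that had been fixed beforehand. Of 79 cytosolic ribosomal protein genes, 58 had a wild-type peak, against 6.02 on average in random sets of genes matched on length and coding class (one-sided permutation test on gene sets, adjusted p = 0.000167 over 10 lists, from the smallest p that 10000 sets can give). Examples by fold enrichment are RPL5 (27.4), RPS24 (26.5), RPL19 (24.8) and RPS21 (23.6). Of 57 genes recalled from a published set of MYC target genes, 35 had a peak against 4.30 at random. Among these were the mitochondrial chaperonin gene HSPD1 (27.1) and the nucleolar protein genes NOP16 (24.3) and NOP56 (20.1). Of 36 genes of SR and hnRNP splicing factors, 20 had a peak against 2.78, including HNRNPM (15.6), HNRNPF (11.7) and SRSF2 (10.6). Of 61 replication-dependent histone genes, whose messages lack a poly(A) tail, 30 had a peak against 3.94, led by H2BC11 (19.0) and H2AC20 (17.5). Of 39 genes of abundant cytoplasmic messages, 23 had a peak against 2.87, among them HSP90AB1 (19.2) and HSPA8 (19.1), both chaperone genes. Of 22 genes listed as abundant nuclear non-coding RNAs, 8 had a peak against 0.227, led by the small nucleolar RNA host gene SNHG3 (21.1). The others were SNHG8, SNHG16, GAS5, SNHG6, PVT1, RPPH1 and RMRP, of which RPPH1 and RMRP were classed above as small non-coding RNA genes. Where these RNAs lie in the cell was not measured, so these hits do not show a preference for nuclear RNA. Each of these 5 lists also had an adjusted p of 0.000167. Expression was not known, and a list of expressed genes can exceed random genes for that reason alone.

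The other 4 lists did not exceed random sets. Of 25 genes of the RNA exosome and nuclear RNA turnover, 3 had a peak, EXOSC4, EXOSC7 and EXOSC3, against 1.80 at random (permutation test, adjusted p = 0.382). No wild-type peak lay in any of 33 innate RNA-sensing and interferon genes, where 2.42 were found at random (adjusted p for fewer = 0.403), in any of 39 marker genes of other tissues, where 2.74 were found (adjusted p for fewer = 0.403), or in any of 34 small non-coding RNA genes such as those of the spliceosomal RNAs, where 0.135 were found. Both mutant lists had 0 genes of these 4 lists.

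**Figure D3:**
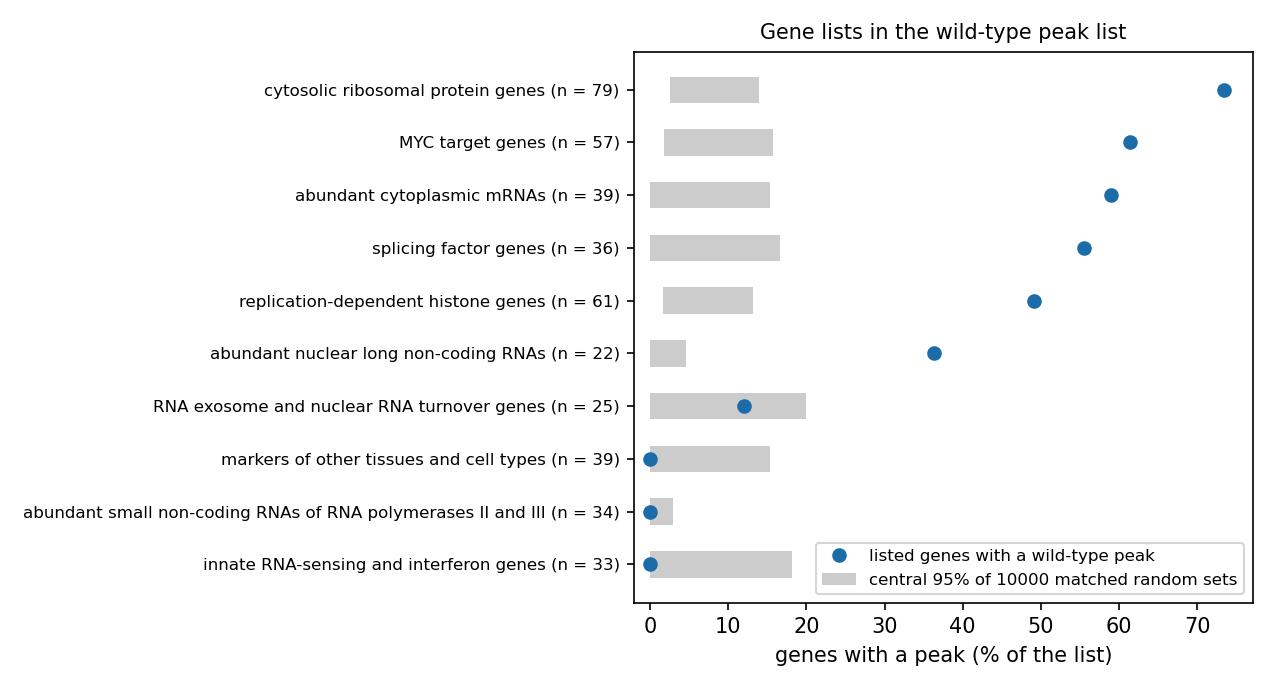
Points give the percentage of the genes of each list that had a wild-type peak, and grey bars the central 95% of 10000 random gene sets matched on length and coding class; n is the number of genes in the list. Cytosolic ribosomal protein genes had the highest share, with 58 of 79, and 6 of the 10 lists lie to the right of their random range.

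Peaks of the 3A mutant lay mainly on wild-type peaks. By an overlap of at least 1 bp, 81 of 103 3A peaks (78.6%, 95% Wilson interval 69.8 to 85.5) met a wild-type peak, all on the same strand. In the other direction they met 76 of the 2149 wild-type peaks (3.54%), against 27.9 ± 2.93 when the 3A peaks were placed at random within their host genes (one-sided permutation p = 0.000999). The genes with the most 3A peaks were ENO1 with 6 and RPL8 with 4. Histone genes held 15 of the 103 3A peaks (14.6%) and 35 of the wild-type peaks (1.63%; Fisher's exact test, adjusted p = 1.73e-08 over 20 tests), and abundant cytoplasmic messages held 25 (24.3%) against 99 (4.61%; adjusted p = 1.01e-09). Neither difference remained against the 103 wild-type peaks of highest −log10 q, of which 10.7% and 20.4% lay in these lists (Fisher's exact test, adjusted p = 1 for each). These shares were compared after the data had been seen. Histone genes of the same type can be similar to each other, so reads can be shared between them.

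Away from wild-type peaks there were 22 3A peaks. By fold enrichment they were led by AP2M1, an adaptor subunit of clathrin-coated vesicles, on chromosome 3 from 184174901 to 184175011 (18.7). A pair of peaks in AUTS2 on chromosome 7 (17.7 and 16.6), a peak in TBC1D22A on chromosome 22 (13.8), CYKILR (13.5) and the galectin gene LGALS1 (12.5) followed. The 3A peak of highest −log10 q, 1381, lay in no annotated gene, on chromosome 12 from 57754989 to 57755094.

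Fewer 7A peaks lay on wild-type peaks. Of 88 7A peaks, 30 met a wild-type peak (34.1%, 95% Wilson interval 25.0 to 44.5), all on the same strand, and 58 did not. The share was 44.5 percentage points below that of 3A (two-sided Fisher's exact test, p = 4.13e-10). The 30 wild-type peaks met still exceeded the 7.69 ± 1.62 of random placements within the host genes (one-sided permutation p = 0.000999). The strongest 7A peaks besides MYC included a peak of 2872 bp in TOM1 on chromosome 22 from 35340018 to 35342889 (30.0), which did overlap a wild-type peak. Among those away from wild-type peaks, 2 peaks in the long non-coding RNA gene LOC124900480 on chromosome 22 had fold enrichments of 24.5 and 23.5. A pair outside genes on chromosome 2, from 8597220 to 8598430 and from 8595210 to 8596736, had 23.5 and 22.8. AUTS2 (21.7), the SUMO ligase gene PIAS4 (19.3), TBC1D22A (18.2), KIRREL3 and the peroxidasin gene PXDN (16.1) came next. PIAS4 also held a wild-type peak, on chromosome 19 from 4036939 to 4037370, which peaks of both mutants met. No 7A peak lay in a cytosolic ribosomal protein gene, against 114 of the wild-type peaks (5.30%; Fisher's exact test, adjusted p = 0.143). Against the 88 wild-type peaks of highest −log10 q, of which 15.9% lay in these genes, the adjusted p of the exact test was 0.00139.

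The mutants shared positions with each other. Of 103 3A peaks, 33 were met by a 7A peak, against 6.50 ± 1.45 at random (one-sided permutation p = 0.000999). In all 3 lists 20 genes had a peak. By wild-type fold enrichment the first 10 were MYC, PGK1, the prohibitin gene PHB2, SCARNA28, DCLK2, the calmodulin gene CALM2, PKM, the cofilin gene CFL1, ZNF316 and H1-4. At gene level, 64 of the 76 3A host genes and 28 of the 61 7A host genes were also wild-type hosts, and 5 genes were hosts in both mutant lists and not in wild type.

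Wild-type peaks that met a mutant peak had higher fold enrichment than the others. The mean log2 fold enrichment was 3.33 (SD 1.38) in 85 shared peaks and 3.02 (SD 0.74) in the 2064 others, a difference of 0.32 (two-sided permutation test, p = 0.00025). The difference fell to 0.12 (permutation p = 0.153) without the peaks at MYC and PGK1. The median −log10 q was 74.8 in shared peaks and 17.2 in the others.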

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

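Of 224 alternative values of 52 results, 179 did not reverse and kept their side of the threshold and, for counts, a size within 1.5 times. In 3 of the 179, against equal numbers of wild-type peaks, a difference went to 0. Chosen after seeing the data were the settings without MYC and PGK1, with −log10 q in place of fold enrichment, with host genes of at least 5 kb, with the summit in the gene, and every share of peaks per gene list. Restriction to the autosomes and X moved nothing, since all peaks lie there, and tests nothing. Placement within an annotation class, summits in exons, GC content and 5-base words were not run for lack of exons and sequence. No paired analysis was possible because each allele has 1 list with no values per replicate, and for the same reason no replicate could be left out. Depth is unknown, so the low number of mutant peaks limits every comparison with them.

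Keeping peaks at or above the median fold enrichment of their list left, by construction, 1076 wild-type, 52 3A and 44 7A peaks. Of these, 32 wild-type peaks met a 3A peak, 7 met a 7A peak and 15 3A peaks met a 7A peak, all with permutation p = 0.000999. Genes with a wild-type peak then numbered 38 for ribosomal proteins, 17 for histones, 15 for abundant cytoplasmic messages, 11 for splicing factors and 3 for nuclear non-coding RNAs, with adjusted p of at most 0.0005. The 3A excess in small non-coding RNA genes was 1.74 percentage points, the 7A difference there was -0.186, and 0% of 7A peaks lay near a gene start.

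Against equal numbers of wild-type peaks of highest −log10 q, 38 met a 3A peak and 10 a 7A peak. The 7A differences were 10.2 points for long non-coding RNA genes, 10.2 outside genes, -11.4 for protein-coding genes and -4.55 for small non-coding RNA genes. Those of 3A were 3.88 outside genes, 0.971 for protein-coding and for long non-coding RNA genes and -1.94 for small non-coding RNA genes. No class difference passed, with fewer peaks compared. Near gene starts the 3A difference was -9.01. By gene list the 3A differences were 3.88 for histones and for abundant messages, -11.7 for ribosomal proteins, and -0.971 for splicing factors and for nuclear non-coding RNAs. Those of 7A were -15.9 for ribosomal proteins, which passed, -9.09 for histones, -10.2 for abundant messages, -1.14 for nuclear non-coding RNAs and 1.14 for MYC targets. At a −log10 q of at least 5 the 7A difference for nuclear non-coding RNAs was -0.629.

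Small non-coding RNA genes gave 3A differences of 0.831 by largest overlap and 1.76 with protein-coding genes first, and 7A differences of -0.140 and -0.186. The 3A call there thus ended under these settings (adjusted p = 0.342 and 0.0551) and in the upper part of each list (adjusted p = 0.243, all by Fisher's exact test). With protein-coding genes first the 3A difference for long non-coding RNA genes was 0.732. The 3A difference at gene starts was -0.000972 within 200 bp and -5.86 in genes of at least 5 kb. Within 1000 bp, 11.7% of 7A peaks lay near a start, below random placement. Without MYC and PGK1 the log2 difference of shared peaks was 0.12 (permutation p = 0.153). The cause was not tested where none is given.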

Other observations

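In this part, the gene families, the strand counts, the tests at MYC and PGK1, the share of mutant peaks on wild-type sites, the test on wild-type peaks met by 7A, the test on carried-over DNA and the test on independent positions were chosen after the values were seen. Further families of housekeeping genes had more wild-type peaks than random sets matched on length and coding class, with 16 families tested. Of the 8 subunits of the CCT chaperonin, which folds actin and tubulin, 7 had a peak against 0.592 at random (one-sided permutation test on gene sets, adjusted p = 0.000178). By the same permutation test so had 5 of 6 MCM genes of the replicative helicase (adjusted p = 0.00032), 9 of 18 cytosolic aminoacyl-tRNA synthetase genes, 9 of 18 ATP synthase genes, 15 of 39 proteasome genes, 13 of 36 complex I genes and 22 of 77 mitochondrial ribosomal protein genes (adjusted p = 0.000178 for each). In contrast, 6 of 477 genes named ZNF had a peak against 34.4 at random, and 0 of 390 olfactory receptor genes against 27.5 (adjusted p for fewer = 0.0008 for each). Expression was not measured here, so these families also differ in ways that were not tested.

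Peaks of a gene mostly shared a strand. All 390 genes with at least 2 wild-type peaks had them on 1 strand, where random strands would give 145, and so had all 15 such 3A genes and 12 of 13 such 7A genes, AUTS2 being the exception. Among wild-type pseudogene peaks 36.0% lay in ribosomal protein pseudogenes, which make up 11.7% of the pseudogenes in the table.

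The strongest wild-type peaks lie at MYC and at the start of PGK1. Native PGK1 messenger RNA alone is argued against, since the highest fold enrichment in the rest of the gene is 2.12% of that at its start. RNA from the expression vector is a candidate source, as PGK1 promoters are common in such vectors, and 74.0% of the peak lies outside the annotated gene on its upstream side. The vector sequence was not used here. Binding of MYC to its own message stays open and untested.

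The mutant lists are short. The upper 95% limits of the shares of 3A and 7A peaks that lie on wild-type peaks are 85.5% and 44.5%. These values do not decide why the lists are short, since peaks elsewhere do not bear on how many wild-type sites were kept and no pair of lists of the same allele shows how far such lists overlap. Wild-type peaks met by 3A had higher −log10 q than the others, with an area under the curve of 0.907. For the number of peaks in both lists and for the wild-type peaks met by 3A, thinner sampling and weaker binding at every site cannot be told apart, since depth is unknown. For the wild-type peaks met by 7A, thinner sampling by −log10 q alone is argued against. Of the 26 in genes, 6 (23.1%) lay near a gene start, against 46.7% of random wild-type peaks matched on −log10 q (95% of sets 26.9 to 65.4, one-sided permutation p = 0.0099). Of 73 met by 3A, 39 did (53.4%, against 47.0%). The random peaks were not matched on gene length, and the 26 include the peaks at MYC, where reads can come from the transgene. Across the whole 7A list the share near gene starts was 50.2 percentage points below that of the 88 wild-type peaks of highest −log10 q (two-sided Fisher's exact test, p = 5.42e-12). That list includes 58 peaks off the wild-type sites, so this difference does not bear on which wild-type sites were kept. Different binding by 7A, and background at positions common to the lists, were not separated.

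Many mutant peaks lie away from wild-type peaks. Carried-over DNA is argued against at loci with at least 2 such peaks within 10 kb. In 9 of 9 of these loci all peaks lay on 1 strand, with a lower 95% limit of 70.1%. Peaks of a locus can be parts of 1 broad region, so their strands may not be independent. Peaks alone at their locus are not covered, and a minus-strand 7A peak in AUTS2 lay farther than 10 kb from the plus-strand ones. Independent positions spread evenly over genes, or over chromosomes for peaks outside genes, are also argued against. Of the 22 3A peaks away from wild-type peaks, 11 met a 7A peak, and random placement gave 0.25 on average and at most 2. Positions drawn independently from the same favoured stretches of genes were not tested. The same count argues against a separate background in each mutant cell line, at positions particular to that line, for the 11 shared 3A peaks. For mutant peaks that the other mutant list did not meet, a separate background stays open. In the test fixed beforehand, the 50% of 3A peaks off the wild-type sites that met a 7A peak were not shown to exceed the 27.2% on them (two-sided Fisher's exact test, p = 0.0692). That test cannot decide the question, since peaks on wild-type sites were also shared between the mutants. Sites that bind the mutants, and background common to both mutant lines, may each contribute and were not separated.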
